A study of Mus musculus with 6 samples.

How the data were processed

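Total RNA of adrenal glands from 3 BPH and 3 BPL mice, male and aged 12 weeks, was labelled with biotin and hybridised to Affymetrix mouse arrays, per the labels' protocols. The deposited table holds 1 linear signal intensity per probe set and array, made with MAS5, per the submitters' processing notes. The MAS5 version, its settings and the scaling target are not given in the sources used here. Checked on the values, the mean after trimming 2% at each end was between 2501.34 and 2501.53 on every array, and signals ran from 0.655 to 172631. Detection calls were not used here.

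The table has 12488 probe sets. The 66 control probe sets were left out of the tests. Of the other 12422, the platform annotation gives 1 gene symbol for 10833, several for 396 and none for 1193, and genes were named only from probe sets with 1 symbol. The mouse gene table of assembly GRCm38.p6 held the symbols of 10817 of those probe sets, none of which it changed, and was used only for names and for which genes are neighbours. No genome build is stated for the array table, so no coordinates are given. Dbh, Cyp11b1 and Cyp11b2 had no probe set with a single symbol and are not reported here.

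The tests, the gene lists, the naming rule and most alternative settings were fixed before the data were examined. Array medians of probe sets differed by 21.0% (945 to 1144), above the tolerance of 10% set for keeping the authors' scaling, so each array was scaled to the mean of the medians, 1040. Values were then log2(signal + 203), where 203 is the 20th percentile of all signals. A fold change on this scale understates the change of dim genes. The 40% of probe sets with the lowest mean over the 6 arrays were not tested, leaving 7453 for 5664 genes. With limma (version 3.58.1, R 4.3.3), lmFit and eBayes compared BPH with BPL in a 2-sided moderated test with 4 residual and 4.50 prior degrees of freedom, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Errors of log2 differences are standard errors from this model, and other errors are SD over 3 arrays. Signals are printed after scaling.

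For 36 gene lists, camera in limma tested the shift of each list with 5 or more tested genes (32 lists), 2-sided, with a preset correlation of 0.01 and 1 probe set per gene, the one with the highest mean. Camera was also run with the correlation estimated for each list. For 16 symbols of the lists the older name used by the annotation was taken. The 3'/5' ratios of the Gapdh and Actb control probe sets and the hybridisation controls were compared by exact permutation, in which 3 against 3 arrays cannot give a p under 0.1. The hybridisation controls gave p from 0.5 to 0.9.

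Named genes were the 10 with the largest increase and the 10 with the largest decrease among those called, with 1 symbol and groups that do not overlap, leaving out clone names and predicted genes. To these were added up to 4 called members of each list with the largest differences, and always, where measured, Th, Ddc, Dbh, Pnmt, Chga, Star, Cyp11a1, Hsd3b1, Cyp21a1, Cyp11b1, Cyp11b2 and Agt. Uncalled list members given as contrasts were chosen after their values were seen.

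No array pair shared more than 1 identical value, so each array was counted as a sample. The alternative settings fixed at that stage were quantile normalization, centring, another pseudocount, a floor, no filter and a stricter filter (lowest 60%), a trended and robust variance, a replicate block, each array left out, an estimated correlation and the mean of a gene's probe sets. Added after the data were seen were the authors' scaling, leaving out BPL replicates 1 and 2, and a skeletal muscle covariate. The model was tested on a single simulated data set, in the comparison of BPH with BPL over 7453 probe sets. Noise had the spread of these arrays but was drawn independently for each probe set. The model recovered 42.9% of 2-fold and 82.8% of 4-fold changes, and 0.8% of its calls were false. Genes on the real arrays vary together, so these shares do not give the error rate of the calls reported here.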

Results

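Adrenal glands of 12-week-old male mice of a hypertensive strain (BPH) and a hypotensive strain (BPL) were profiled on Affymetrix arrays, with 3 arrays per strain. The strains go back to selection for high and low blood pressure, and the comparison asks which adrenal transcripts differ between them. The labels give 3 mice per strain but do not say whether an array held the RNA of 1 animal, so the p-values measure the spread between these samples, part of which may be technical. Of 12422 probe sets that were not controls, 7453 were bright enough to be tested, and they covered 5664 genes. The number of arrays limits the precision, and no detection call was used. Pearson correlations of log2 signals, across probe sets, ran from 0.957 to 0.969 among BPH arrays, from 0.929 to 0.946 among BPL arrays and from 0.869 to 0.943 between strains.

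BPH adrenals had higher signals of several stress-responsive genes, and BPL adrenals had higher signals of several skeletal muscle genes. Hspa1a, an inducible chaperone of the Hsp70 family, was at a signal of 1639 ± 224 in BPL and 57483 ± 23384 in BPH (SD, n = 3), a log2 difference of 4.89 ± 0.30 (SE, limma with Benjamini-Hochberg adjustment, adjusted p = 1.1e-04). Fos, a subunit of the AP-1 transcription factor, rose from 814 ± 238 to 11684 ± 5150 (SD, n = 3), a log2 difference of 3.47 ± 0.35 (limma adjusted p = 0.0013). Acta1, the actin of skeletal muscle fibres, was at 52319 ± 42219 in BPL and 247 ± 126 in BPH (SD, n = 3), a log2 difference of -6.47 ± 0.63 (limma adjusted p = 0.0012). Star, Cyp11a1, Hsd3b1 and Cyp21a1, genes of steroid synthesis with signals among the highest on the arrays, did not pass the test. Cyp11b1 and Cyp11b2 had no probe set with a single symbol and were not tested.

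In all, 306 probe sets passed the limma test, 237 higher and 69 lower in BPH, and 1532 had an unadjusted p under 0.05. They named 262 genes, 204 higher, 57 lower and 1 with probe sets in both directions. A difference of at least 2-fold was found for 201 of the probe sets, 156 higher and 45 lower. The share of calls that were higher in BPH was 77.5%, against 66.3% of 294 calls (195 higher, 99 lower) with the authors' own scaling, 67.3% of 269 (181 higher, 88 lower) after quantile normalization and 69.1% of 275 (190 higher, 85 lower) after centring. The median log2 difference of all tested probe sets was 0.08, and it was -0.02 with the authors' scaling. Without BPL replicates 1 and 2, which had the highest skeletal muscle signals, 87 probe sets were called, 77 higher and 10 lower, of which 69 were among the 306.

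Of 20 tested immediate early genes, which are transcribed within minutes of a stimulus, 15 were higher and 0 lower, and 16 were higher when adjusted over the list alone. The median log2 difference was 1.9 (camera adjusted p = 3.5e-15, and adjusted p = 0.54 with an estimated correlation). Besides Fos, the AP-1 subunit Junb rose by 3.41 ± 0.23 (limma adjusted p = 1.6e-04), the zinc finger factor Egr1 by 3.16 ± 0.22 (limma adjusted p = 2.1e-04) and the nuclear receptor Nr4a2 by 3.06 ± 0.23 (limma adjusted p = 3.2e-04). The other probe sets of Junb and Nr4a2 rose by 5.10 and 3.47. Gadd45b, a stress-induced gene outside the list, rose by 3.68 ± 0.16 (limma adjusted p = 2.3e-05), and its other probe set by 3.39. Jun, at 0.47 ± 0.28, and Myc, at 0.08 ± 0.20, did not pass.

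Of 25 tested heat shock and protein folding genes, 9 were higher and 0 lower, and 13 were higher and 1 lower when adjusted over the list alone. The median log2 difference was 0.53 (camera adjusted p = 6.4e-05, and adjusted p = 0.54 with an estimated correlation). Hspa1b rose by 4.67 ± 0.33 (limma adjusted p = 2.1e-04), the Hsp40 co-chaperone Dnajb1 by 3.17 ± 0.44 (limma adjusted p = 0.0067) and Hsph1, a nucleotide exchange factor of the Hsp70 family, by 2.44 ± 0.27 (limma adjusted p = 0.0019). The other 16 genes did not pass over all probe sets, among them Hspa5 at 0.17 ± 0.17 and Pdia6 at -0.50 ± 0.17. Alongside these groups, the log2 ratio of the 3' to the 5' Gapdh control probe set was -0.001 ± 0.050 in BPL and 0.169 ± 0.074 in BPH (SD, n = 3), and that of Actb was 0.856 ± 0.057 and 1.08 ± 0.16. Each ratio was higher in all 3 BPH arrays (2-sided exact permutation test, p = 0.1, the smallest that 3 against 3 arrays allow, adjusted p = 0.3). Without BPH replicate 2, 5 heat shock genes were called higher. With the skeletal muscle covariate 0 were called by limma in either list on the 1 probe set used per gene, while the other probe set of Junb was called. Camera with the preset correlation still called both lists there. That covariate differs between the strains and so takes up part of their difference. Without BPL replicates 1 and 2, 13 of the 20 immediate early genes and 3 of the 25 heat shock genes (Hspa1a, Hspa1b and Hsph1) were called higher.

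**Figure D1:**
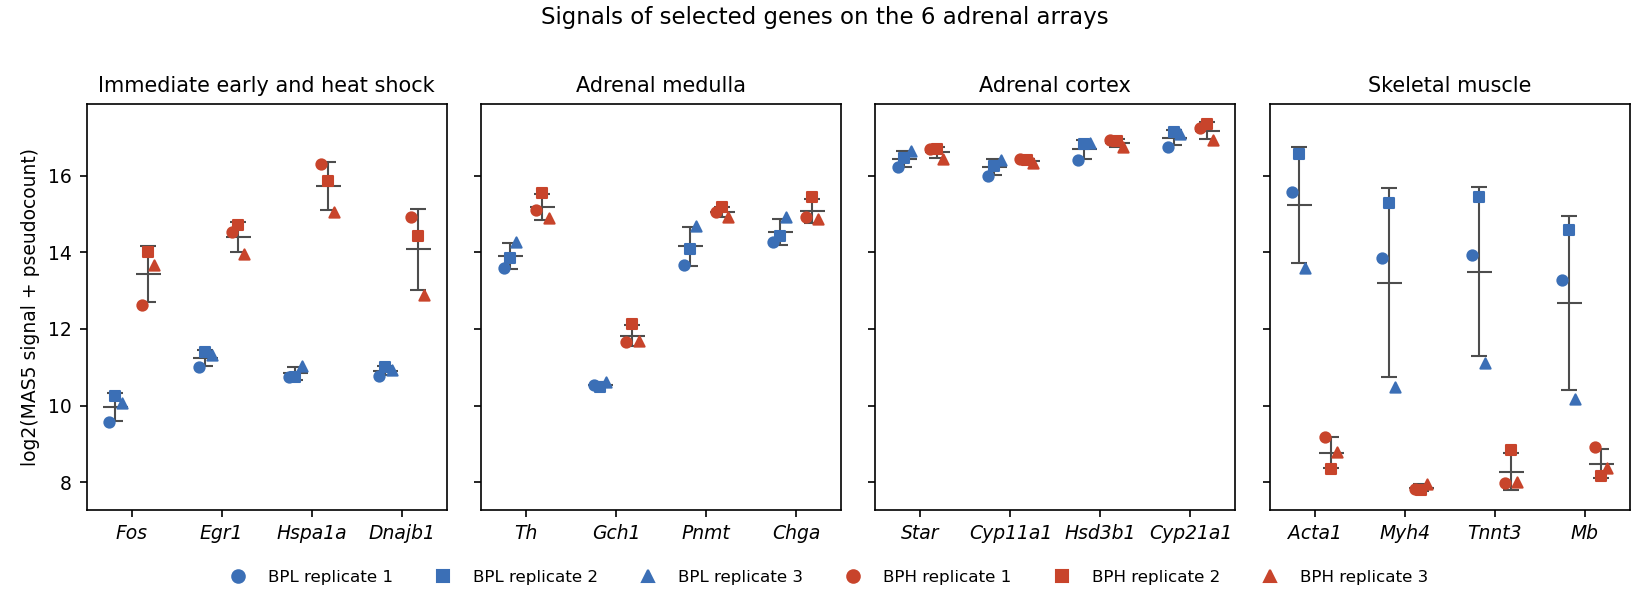
Log2 signals (MAS5 signal plus pseudocount, y axis) of 16 genes on the 3 BPL and 3 BPH arrays, with symbols for replicates and bars for the mean ± SD of each strain. Fos, Egr1, Hspa1a and Dnajb1 lie higher on every BPH array than on any BPL array, the cortical genes overlap, and the 4 skeletal muscle genes lie far apart among the BPL arrays, with replicate 2 highest.

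Some genes of the adrenal medulla were called higher in BPH and others did not pass. Th, the rate-limiting enzyme of catecholamine synthesis, rose from a signal of 15405 ± 3846 to 37643 ± 9127 (SD, n = 3), a log2 difference of 1.28 ± 0.24 (limma adjusted p = 0.023), and Gch1, which starts the synthesis of the cofactor of Th, rose by 1.28 ± 0.17 (limma adjusted p = 0.0058). Neuropeptide Y (Npy) rose by 1.47 ± 0.27 (limma adjusted p = 0.023). Other medullary genes did not pass: Pnmt, which turns noradrenaline into adrenaline, differed by 0.90 ± 0.25 (limma adjusted p = 0.097), the granule protein Chga by 0.53 ± 0.23 (limma adjusted p = 0.23) and Ddc, the enzyme after Th, by 0.27 ± 0.25 (limma adjusted p = 0.57). The second probe sets of Pnmt and Chga gave 1.19 and 0.08, not called either.

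Of 13 tested chromaffin cell markers, 4 were higher and 0 lower, and 5 were higher when adjusted over the list alone, with a median log2 difference of 0.53 (camera adjusted p = 0.0012, and adjusted p = 0.54 with an estimated correlation). The called markers were Th, the neuronal hydrolase Uchl1 (1.20 ± 0.18, limma adjusted p = 0.0088), the granule protein Scg2 (0.84 ± 0.19, limma adjusted p = 0.048) and the adhesion molecule Ncam1 (0.77 ± 0.16, limma adjusted p = 0.035), whose other probe set stood at -0.32 and was not called. Of 13 secretory granule proteins and neuropeptides, which share Chga, Chgb and Scg2 with the chromaffin list, 3 were higher and 0 lower, and 4 were higher when adjusted over the list alone. Their median was 0.63 (camera adjusted p = 0.0012, and adjusted p = 0.54 with an estimated correlation), and Resp18 rose by 1.10 ± 0.23 (limma adjusted p = 0.034). Of 10 genes of catecholamine synthesis, storage and breakdown, 2 were higher, and 4 when adjusted over the list alone, and the list was not called (median 0.30, camera adjusted p = 0.16). None of 8 genes of the exocytosis machinery was called, which is 0 by limma on either adjustment (median 0.12, camera adjusted p = 0.75). Th, Npy, Resp18, Scg2 and Ncam1 were no longer called without BPL replicate 1, without BPL replicate 2, without BPH replicate 1 or without BPH replicate 2. With the replicate block 2 chromaffin markers and 1 granule gene were called higher. The skeletal muscle covariate differs between the strains and so takes up part of their difference, and only 2 of the 7453 tested probe sets were called with it. Both called lists lost their call with that covariate, at medians of 0.03 for chromaffin markers and 0.11 for granule proteins. Without BPL replicates 1 and 2 both stayed called, at medians of 0.35 each (camera adjusted p = 0.037 for chromaffin markers and 0.018 for granule proteins), with 0 members called by limma. The granule median was 0.40 without BPL replicate 2 alone.

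Among steroid-making genes of the cortex, Star, which brings cholesterol into mitochondria, had a log2 difference of 0.17 ± 0.17 (limma adjusted p = 0.61), Cyp11a1, the side chain cleavage enzyme, 0.17 ± 0.16 (limma adjusted p = 0.57), Hsd3b1 0.17 ± 0.17 (limma adjusted p = 0.60) and Cyp21a1, the 21-hydroxylase, 0.18 ± 0.18 (limma adjusted p = 0.60). The other probe sets of Star and Hsd3b1, at 0.02 and 0.31, were not called either. These probe sets lay at 16.2 to 17.2 on the log2 scale, near the top of the range, where a difference can be compressed. Of 13 steroid synthesis genes 1 was called, on either adjustment: Mrap, the partner protein of the ACTH receptor, rose by 0.92 ± 0.16 (limma adjusted p = 0.020, list median 0.18, camera adjusted p = 0.11). The list median was 0.04 after quantile normalization, 0.07 without BPL replicate 1 and 0.27 without BPL replicate 3.

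Within cholesterol synthesis, Idi1 rose by 1.78 ± 0.25 (limma adjusted p = 0.0067) and Sqle, the squalene epoxidase, by 1.0 ± 0.20 (limma adjusted p = 0.029). These were 2 of 16 genes, with 0 lower, and 5 were higher when adjusted over the list alone (median 0.19, camera adjusted p = 0.045, and adjusted p = 0.54 with an estimated correlation). The list lost its call without BPL replicate 1 (camera adjusted p = 0.050), BPL replicate 2 (0.069), BPH replicate 2 (0.081) or BPH replicate 3 (0.088), with the stricter filter (0.076), without BPL replicates 1 and 2 together (0.27) and with the skeletal muscle covariate (0.86). Its median was 0.08 with the authors' scaling, 0.09 after centring, 0.30 without BPL replicate 3, 0.09 without BPL replicates 1 and 2 and -0.05 with the covariate. Lipe, the hormone-sensitive lipase that frees stored cholesterol and fat, fell by 0.86 ± 0.18 (limma adjusted p = 0.035) and was the only call among 15 genes of lipoprotein uptake and cholesterol ester handling, on either adjustment. That list had a median of 0.02, a mean of -0.04 and a downward test (camera adjusted p = 0.44), and its median was -0.09 with the authors' scaling.

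The glomerulosa and fasciculata markers went both ways. Of 9 markers of the glomerulosa, the aldosterone-making zone, 2 were higher and 1 lower, and 3 were higher and 1 lower when adjusted over the list alone (median 0.40, camera adjusted p = 0.12). Nr4a2 (also an immediate early gene) and the calcium sensor Vsnl1 (1.36 ± 0.27, limma adjusted p = 0.029) rose, and the secreted signal Shh fell by 1.13 ± 0.18 (limma adjusted p = 0.014). Of 7 fasciculata markers 1 was higher and 1 lower on either adjustment (median 0.17, camera adjusted p = 0.94): the peroxisomal oxidase Hao2 rose by 1.12 ± 0.21 (limma adjusted p = 0.023), and the microsomal glutathione transferase Mgst1 fell by 1.89 ± 0.19 (limma adjusted p = 0.0013). The only tested X-zone marker, Cyp2f2, had a log2 difference of -0.48 ± 0.26 (limma adjusted p = 0.33).

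Among the 10 genes with the largest decreases, 9 belong to striated muscle. The fast myosin heavy chains Myh4 and Myh1 had log2 differences of -5.35 ± 0.99 (limma adjusted p = 0.023) and -4.87 ± 0.95 (limma adjusted p = 0.028), the fast troponin Tnnt3 of -5.21 ± 0.91 (limma adjusted p = 0.019) and the slow myosin light chain Myl2 of -4.34 ± 0.91 (limma adjusted p = 0.036). Myoglobin (Mb), the muscle cytochrome oxidase subunit Cox6a2, the calcium pump Atp2a1 and the slow myosin Myh7 had -4.20, -4.12, -3.98 and -3.41, all called (limma adjusted p from 0.036 to 0.047). A second Atp2a1 probe set fell by 4.48, and a second Myh4 probe set, at -0.42, was not called. Myh4 had signals of 14627, 40018 and 1224 in BPL replicates 1, 2 and 3, and of 21.8, 19.2 and 45.6 in the BPH arrays. Of 13 smooth and skeletal muscle markers, 5 were lower and 1 higher, and 7 were lower and 1 higher when adjusted over the list alone (median -0.99, mean -2.01, camera adjusted p = 4.5e-04, and adjusted p = 0.54 with an estimated correlation). The lower ones were the skeletal muscle genes Acta1, Myh4, Tnnt3, Mb and Mylpf, and 5 of the 13 markers had positive differences. The higher one was Tagln, a smooth muscle protein, at 0.93 ± 0.19 (limma adjusted p = 0.035). Mylpf and Tagln were chosen for mention after their values were seen. With the authors' scaling, after quantile normalization or after centring, 0 of the list were called higher by limma. The same held with no filter, without BPL replicate 1 and without BPL replicate 2. Myl2, Mb, Cox6a2, Atp2a1 and Myh7 were not called with the authors' scaling, after quantile normalization or after centring, and with a trended and robust variance 8 of the 9 muscle genes, all but Acta1, were not called. The median of this list, which joins smooth and skeletal muscle genes, moved with single arrays. It was -0.65 without BPL replicate 1, -0.42 without BPL replicate 2 and -2.63 without BPL replicate 3. It was -2.59, -2.03 and -2.62 without BPH replicates 1, 2 and 3. In these 6 settings 1 to 8 members were called lower. It was also -2.14 after quantile normalization, -1.71 with the higher pseudocount and -1.54 with the stricter filter. Without BPL replicates 1 and 2 the list was not called (camera adjusted p = 0.61).

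The lists of oxidative phosphorylation and of fatty acid metabolism were called lower in BPH with the preset correlation only, and 1 and 0 of their genes were called. Of 44 oxidative phosphorylation genes, 4 had positive differences and only Sdhd, a subunit of succinate dehydrogenase, was called, on either adjustment, at -1.26 ± 0.24 (limma adjusted p = 0.024). The list median was -0.24 (camera adjusted p = 4.0e-08, and adjusted p = 0.54 with an estimated correlation). Of 20 genes of fatty acid and ketone metabolism, 0 were called by limma over all probe sets and 8 were lower when adjusted over the list alone, among them Ehhadh at -0.97 ± 0.23 and Etfdh at -0.92 ± 0.24 (list median -0.44, camera adjusted p = 5.6e-06, and adjusted p = 0.54 with an estimated correlation). The mean log2 signal of skeletal muscle markers was 13, 13.9 and 10.9 in BPL replicates 1, 2 and 3 and ran from 9.13 to 9.26 in BPH. The lists did not follow it on every array: BPH replicate 1 lay above BPL replicate 3 in mean log2 signal, at 14.05 and 13.96 for oxidative phosphorylation and at 13.78 and 13.71 for fatty acid metabolism. Among BPH replicates 1, 2 and 3 the fatty acid mean was 13.78, 13.38 and 13.32. Among BPH arrays, the signals of the brown fat genes Cidea (44607, 24397 and 22639) and Ucp1 (46044, 27118 and 27570) were likewise highest in replicate 1. In BPL replicates 1, 2 and 3 the signals were 44350, 51183 and 40472 for Cidea and 64979, 63359 and 48780 for Ucp1. Whether the 2 metabolic lists followed the amount of fat tissue in the samples was not tested. Without BPL replicates 1 and 2 neither list was called, with medians of -0.09 for oxidative phosphorylation (camera adjusted p = 0.064) and -0.31 for fatty acid metabolism (camera adjusted p = 0.059). With the skeletal muscle covariate neither was called, at medians of 0.09 and -0.08 (camera adjusted p = 0.86 for each). After quantile normalization the oxidative phosphorylation median was -0.39. Glycolysis was not called (17 genes, median -0.09, camera adjusted p = 0.054). Its median was -0.25 after quantile normalization and -0.23 without BPL replicate 1. The neuronal enolase Eno2 rose by 0.86 ± 0.19 (limma adjusted p = 0.043), the only call of that list on either adjustment. Eno2 lost that call with the authors' scaling, after quantile normalization or centring and with the floor. No filter, the replicate block and the skeletal muscle covariate each ended that call too. It was also lost without BPL replicates 1 and 2 together and without each single array but BPL replicate 1.

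Fat markers were bright in both strains. The adipocyte hormone Adipoq was at a signal of 58866 ± 2562 in BPL and 62722 ± 9958 in BPH (SD, n = 3), and Ucp1, the uncoupling protein of brown fat, at 59039 ± 8922 and 33577 ± 10799, a log2 difference of -0.84 ± 0.24 that did not pass (limma adjusted p = 0.097). Of 11 fat markers 1 was higher and 1 lower, and 2 were higher and 3 lower when adjusted over the list alone (median -0.23, camera adjusted p = 0.084). The carbonic anhydrase Car3 rose by 0.76 ± 0.16 (limma adjusted p = 0.036), and Lipe fell. Both lost their call with the floor, with no filter, with the replicate block and with the skeletal muscle covariate. Their calls were also lost without BPL replicates 1 and 2 together and without each single array but BPL replicate 3. Car3 was not called after quantile normalization either.

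Among immune genes, H2-Q10, a secreted class I histocompatibility molecule, fell by 3.28 ± 0.30 (limma adjusted p = 8.7e-04), and Irf4, a transcription factor of lymphoid cells, rose by 3.14 ± 0.32 (limma adjusted p = 0.0013) from a signal of 79.4 ± 34.3 (SD, n = 3). Neither gene had another tested probe set. Sequence differences between the strains under the probes were not examined, for these genes or any others. H2-Q10 was the only call among 13 class I and antigen processing genes on either adjustment, and that list had a median of 0.19, a mean of -0.04 and an upward test (camera adjusted p = 0.80). Of 14 interferon response genes, only Ifit3 was called on either adjustment, at -1.29 ± 0.21 (limma adjusted p = 0.016). The list was called lower (median -0.16, camera adjusted p = 0.047, and adjusted p = 0.54 with an estimated correlation), a call lost with the authors' scaling (camera adjusted p = 0.071), after quantile normalization (0.18) or centring (0.063), with the higher pseudocount (0.052), no filter (0.055) or the mean of a gene's probe sets (0.057). It was also lost without BPL replicate 3 (camera adjusted p = 0.14), BPH replicate 1 (0.064) or BPH replicate 3 (0.060), and with the replicate block (0.060). With the stricter filter too few members were left to test. The median moved with single arrays, to -0.29 without BPL replicate 1, -0.25 without BPL replicate 2, -0.06 without BPL replicate 3, -0.30 without BPH replicate 1 and -0.02 without BPH replicate 3. It was -0.25 with the authors' scaling or centring, and -0.41 with the skeletal muscle covariate. Of 13 complement and coagulation genes 1 was higher, and 4 when adjusted over the list alone, with the plasminogen activator Plat at 0.89 ± 0.18 (limma adjusted p = 0.030, list median 0.20, camera adjusted p = 0.26). None of 13 macrophage and myeloid markers was called by limma on either adjustment (median 0.32, camera adjusted p = 0.15), nor any of 4 lymphocyte markers (median -0.39).

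The lists of renin-angiotensin, natriuretic and endothelin genes, of receptor and G protein genes, and of ion channels had at most 1 call each over all probe sets. Over all tested genes, 262 of 5664 were called, so such counts in short lists do not show a shortage of calls. Of 10 tested genes of the renin-angiotensin, natriuretic and endothelin systems, the natriuretic peptide clearance receptor Npr3 fell by 1.10 ± 0.21 (limma adjusted p = 0.024), while its other probe set stood at -0.04 and was not called. Adjusted over the list alone, 1 was higher and 1 lower. The list had a median of 0.24, a mean of 0.004 and a downward test (camera adjusted p = 0.94). Agt, angiotensinogen, was too dim to be tested, at signals of 194 ± 21.2 in BPL and 344 ± 162 in BPH (SD, n = 3). Rgs2, which limits signalling through Gq-coupled receptors, rose by 1.56 ± 0.16 (limma adjusted p = 0.0013), the only call among 11 adrenergic, cholinergic and G protein genes on either adjustment (median 0.21, camera adjusted p = 0.20). None of 12 ion channels and pumps was called by limma on either adjustment (median 0.13, camera adjusted p = 1.0).

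The metallothioneins Mt1 and Mt2, which bind zinc and copper, rose by 1.21 ± 0.22 (limma adjusted p = 0.023) and 1.17 ± 0.21 (limma adjusted p = 0.022). With Mgst1 lower they were the calls among 33 glutathione and antioxidant genes on either adjustment (median 0.15, camera adjusted p = 0.82). The 2 probe sets annotated as Srxn1, sulfiredoxin, disagreed: 1 rose by 3.18 ± 0.17 (limma adjusted p = 7.9e-05) and the other stood at -0.03 (limma adjusted p = 0.93). The value of the rising probe set lay near those of the 2 Gadd45b probe sets (3.39 and 3.68), and whether its annotation is right was not settled. Capg, an actin-capping protein, rose by 3.11 ± 0.24 (limma adjusted p = 3.2e-04). The clock gene Per1, also an immediate early gene, rose by 1.15 ± 0.16 (limma adjusted p = 0.0067) and was the only call of 14 clock genes, with 3 higher and 1 lower when adjusted over the list alone (median -0.004, mean 0.10, downward test, camera adjusted p = 0.82).

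In the remaining groups single genes were called. The ribosomal protein Rps19 rose by 1.19 ± 0.15 (limma adjusted p = 0.0040) among 19 ribosomal genes, with 3 higher when adjusted over the list alone (median 0.21, camera adjusted p = 0.15). The proteasome subunit Psmb6 rose by 1.30 ± 0.17 (limma adjusted p = 0.0043), the only call of 26 on either adjustment (median 0.17, camera adjusted p = 0.20). The replication clamp Pcna rose by 0.90 ± 0.17 (limma adjusted p = 0.026) among 19 cell cycle genes, with 2 higher when adjusted over the list alone (median 0.18, camera adjusted p = 0.33). Pcna lost its call when any 1 array was left out and without BPL replicates 1 and 2 together. It also lost it with no filter, with the replicate block and with the skeletal muscle covariate. The matrix proteoglycan Bgn rose by 0.96 ± 0.21 (limma adjusted p = 0.042), with its other probe set at 0.50 and not called, among 25 matrix genes of which 2 were higher and 1 lower when adjusted over the list alone (median 0.09, downward test, camera adjusted p = 1.0). That median was -0.02 with the authors' scaling. None of the remaining marker genes was called by limma over all probe sets. Of 11 endothelial markers 2 were higher and 1 lower when adjusted over the list alone (median 0.06, -0.04 with the authors' scaling, camera adjusted p = 1.0), and of 7 Schwann and sustentacular cell markers (median -0.20, camera adjusted p = 0.12) and 7 pancreas and liver markers (median -0.17, camera adjusted p = 0.20) none. Medians were -0.37 for 4 kidney markers, of which Pvalb, also a gene of fast muscle, was lower when adjusted over the list alone, and 0.31 for 3 red blood cell genes.

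**Figure D2:**
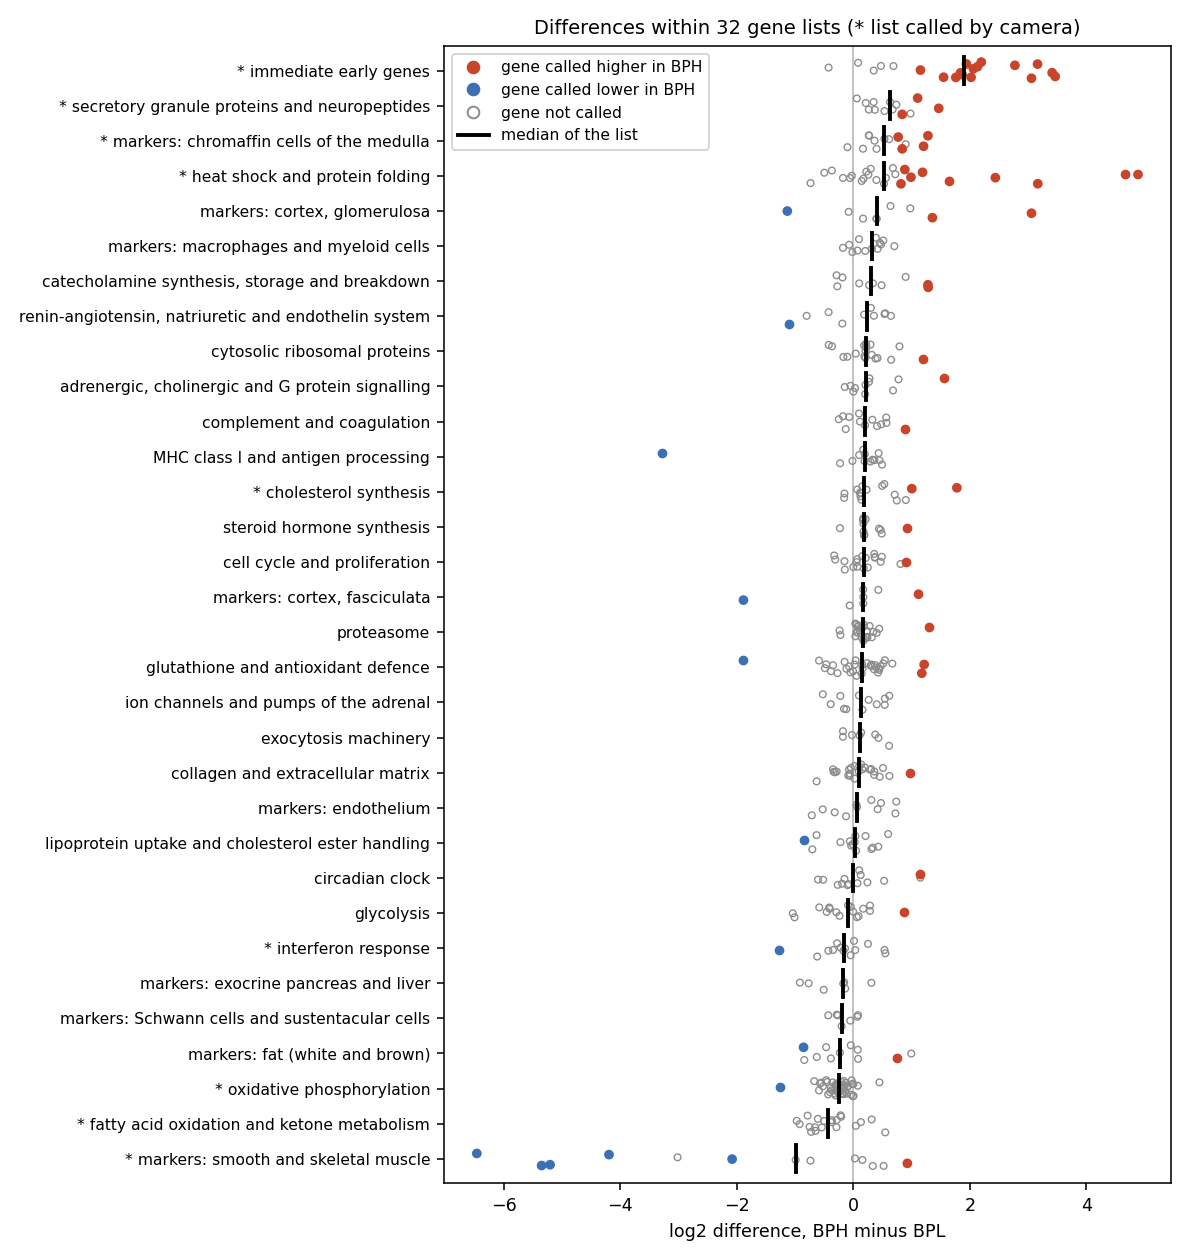
Log2 differences (BPH minus BPL, x axis) of the tested members of 32 gene lists (y axis), with filled points for genes called higher or lower, open points for genes not called, black bars for list medians and stars for lists called by camera with the preset correlation. Immediate early genes have a median of 1.9 and smooth and skeletal muscle markers together of -0.99, while 0 lists are called with an estimated correlation.

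With the preset correlation, camera called 9 of 32 lists, 5 higher and 4 lower. With a correlation estimated for each list it called 0, and the immediate early genes had the smallest p, 0.017 unadjusted and 0.54 adjusted. The calls on lists therefore rest on the preset correlation, while the calls on single genes do not. The run with estimated correlations was stricter also where the estimate lay below the preset 0.01. For Schwann and sustentacular cell markers, at an estimate of -0.03, the unadjusted camera p was 0.053 with the preset correlation and 0.12 with the estimated one. The loss of all list calls thus does not measure correlation alone. The settings ended the calls of most of the 51 genes followed through them. Hspa1a, Hspa1b, Hsph1, Gadd45b, Fos, Junb, Egr1, Nr4a2, Irf4, Capg, Acta1, H2-Q10, Idi1, Rgs2, Mgst1 and the rising Srxn1 probe set kept their call wherever tested except with the skeletal muscle covariate. There only Gadd45b (3.44, against 3.68 without the covariate), and Junb on its other probe set (4.48, against 5.10), were called. The covariate takes up part of the strain difference, so a call lost there does not show that muscle explains a gene. Dnajb1, Gch1, Per1, Rps19, Psmb6 and Uchl1 lost it also without BPL replicates 1 and 2 together, and each other one lost it without at least 1 single array.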

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

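The tests of immediate early genes and of chromaffin markers in this part were chosen after the results were seen, and the 3 added alternatives likewise. The test of other splits of the arrays was chosen before. That of a second muscle list was chosen before its own result, but after the first muscle genes and their order had been seen.

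A control probe set that entered no comparison stood out. The probe set for the 5' end of 18S ribosomal RNA had a log2 signal of 16.5 on BPH replicate 3, against at most 13.4 on the BPL arrays and 12.0 and 12.2 on the other BPH arrays. The probe set for the 3' end stood at 13.8 on that array and at most 13.4 on the others.

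Of 20 immediate early genes 15, and of 25 heat shock genes 9, were called higher in BPH. Under 4 scalings the median of the immediate early list was never below 1.76. The factors of the main scaling ran only from 0.91 to 1.10, so little movement could be expected from the outset. The list difference is larger than these scalings could produce. Dilution of adrenal RNA by other tissue in BPL would lower adrenal genes alike. The immediate early median, however, exceeded that of steroid synthesis genes by 1.72 on the log2 scale. Among the 18 and 6 genes below a log2 value of 15, where compression is smaller, the gap was 1.64 (95% bootstrap interval over genes 1.02 to 2.21). That interval treats genes as independent and leaves out the spread between arrays. Genes varied together, with estimated correlations of 0.23 in the immediate early list and 0.64 in the steroid list. Stress of the animals, or the time and order of handling before the RNA was fixed, may also have differed, and this cannot be told apart from a strain difference, because the labels give no handling order. That 31 of 45 immediate early and heat shock genes were higher on every BPH array than on any BPL array would follow from any cause of the calls and decides nothing, and strain itself stays open.

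Of the 10 genes with the largest decreases in BPH, 9 were striated muscle genes. A candidate explanation is muscle tissue carried along with the BPL glands, for which a second list of 47 muscle genes was written before it was tested. Its tested members all had negative log2 differences, from -4.46 for Ckmt2 to -0.07 ± 0.26 for Ankrd2. The differences of Ankrd2 and of Myod1 (-0.11 ± 0.21) were smaller than their standard errors. Of the 19 tested members of that list 0 were called by limma, and their median log2 difference was -1.20. Of these members, 89.5% followed the order replicate 2, 1, 3 among BPL arrays, against 16.7% by chance. Muscle genes varied together on these arrays (estimated correlation 0.53 in the first muscle list), so the shared order is not 19 separate observations. Any cause that varies muscle transcripts between the BPL samples could give it, so the order does not decide the cause. A fixed level of expression in BPL adrenal cells would give BPL arrays alike, but their median SD over the second list was 3.99 times that of all tested probe sets (1.26 times among BPH arrays). A strain difference that varies between animals was not tested.

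Of 13 chromaffin markers 4 were called higher in BPH, and the list was called with the preset correlation but not with an estimated one (adjusted p = 0.54). A larger share of medulla would raise the markers alike only if all came from chromaffin cells alone and their probe sets responded alike, which was not tested. Of the 13, 3 departed from the mean of the other markers when adjusted over the list alone. Th departed by 0.76 ± 0.23 and Uchl1 by 0.68 ± 0.20 upwards and Hand1 by -0.73 ± 0.22 (SE, limma adjusted p = 0.026 for each). The markers thus did not all move alike, which does not decide whether the share of medulla differed. The test of departures replaced one that relied on a normal approximation with 3 arrays per strain, after that result was seen. Dilution by other tissue in BPL cannot be told apart, since the markers exceeded steroid synthesis genes by 0.31 (SE 0.13), but by 0.26 (SE 0.14) among genes below a log2 value of 15, where compression is smaller. A larger share of medulla and a change in medullary cells both stay open. Stress or handling before the RNA was fixed cannot be told apart from strain here either.

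Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, called as many as 306 probe sets, 262 genes or 201 probe sets with a 2-fold difference, and the highest of the others was 0 for each. For gene lists, 2 splits reached the real 9, and the highest of the others, with BPL replicates 1 and 2 and BPH replicate 1 together, was 10. With 10 splits the share cannot fall below 0.1.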

How the results depend on the processing

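Of the settings here, the authors' scaling, leaving out BPL replicates 1 and 2, and the skeletal muscle covariate were chosen after the data were seen. Leaving out 1 array at a time gave 101 to 375 called probe sets (81 to 283 higher, 20 to 92 lower), 82 to 324 genes, 101 to 272 probe sets with a 2-fold difference and 7 to 9 called lists. The probe sets called were 158 without BPL replicate 1, 144 without BPL replicate 2, 375 without BPL replicate 3, 129 without BPH replicate 1, 101 without BPH replicate 2 and 181 without BPH replicate 3, and such settings have fewer samples. Of the 51 named genes that were called, 22 of 50 tested were still called without BPH replicate 2. With no filter on low values, which adds tests, 127 probe sets were called (106 higher, 21 lower), in 102 genes, 125 of them 2-fold. Without BPL replicates 1 and 2, where the lone BPL array is assumed to vary like the BPH arrays, 87 were called (77 higher, 10 lower), in 72 genes, 87 of them 2-fold, with 5 lists. With the skeletal muscle covariate, which differs between the strains and so takes up part of their difference, 2 were called (2 higher, 0 lower by limma, 378 at an unadjusted p under 0.05), in the 2 genes Gadd45b and Junb, 2 of them 2-fold, with 3 lists: immediate early, heat shock and interferon genes. That covariate turned the sign of the oxidative phosphorylation list (0.087) and the muscle list (0.50), and of Myh4 (0.11), Myh1 (0.31), Myl2 (0.66), Mb (0.82), Cox6a2 (0.63), Atp2a1 (0.88) and Myh7 (0.49), none of them called. With an estimated correlation between genes 0 lists were called, against 9 with the preset one. The stricter filter and the trended and robust variance gave 431 each, the higher pseudocount 382, the floor 240, quantile normalization 269, centring 275 and the authors' scaling 294. Glycolysis was called after quantile normalization, with the higher pseudocount, with the stricter filter, with the replicate block and without BPL replicate 3, and the fat list with the stricter filter and without BPH replicate 1. Pnmt was called with the stricter filter, with the trended and robust variance and without BPL replicate 3. Of the 306 probe sets, all that were tested kept their direction in each setting but the covariate, where 296 did. The cause of the changes was not tested where the construction of the setting does not show it. The replicate numbers did not pair the arrays, with correlations of deviations of -0.06, -0.05 and -0.18 for the same numbers, and no array correlated best with its own number. With the replicate block 239 probe sets were called (172 higher, 67 lower), 211 of them among the 306. Without detection calls, signal over background is not known for single probe sets.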

Other observations

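The test of neighbouring genes was chosen before its result was seen, and H2-Ea was chosen for mention after its value was seen. Beside the fall of H2-Q10, the class II histocompatibility gene H2-Ea had a log2 difference of 2.89 (limma adjusted p = 0.0042, higher in 3 of 3 BPH arrays).

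Strains that inherited different haplotypes could differ in runs of neighbouring genes. Of 240 called genes placed in order, 15 pairs of neighbours were both called, against a median of 10 and a 95% bound of 15 in 10000 random draws (permutation p = 0.078). Among them were Hspa1a with Hspa1b, Mt1 with Mt2 and Myh1 with Myh4, which are duplicated genes. Without the immediate early, heat shock and muscle lists the count was 11, against a median of 8 (permutation p = 0.15). The count did not exceed the bound fixed beforehand, so no clustering was shown, and differences at single loci were not tested.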
